A study of Mus musculus with 6 samples.

How the data were processed

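Messenger RNA from cultured mouse hepatic stellate cells was measured in 6 libraries, 3 labelled wild type and 3 labelled Nbr1 knock-out. Per the labels' protocols, RNA was extracted with Trizol and a column kit, libraries were made from 200 ng with the Lexogen QuantSeq 3' forward kit with optional unique molecular identifiers, and single-end reads of 75 nucleotides were taken on a NextSeq 500. This kit primes on the poly(A) tail, so a value counts transcript ends near the 3' end and does not grow with transcript length. Whether the counting used strand or the molecular identifiers, and which aligner and annotation were used, is not given in the sources used here. The submitters' processing notes name DESeq2, without a version, and the mouse build GRCm39.

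The deposited table gives, per the file headers, 1 column per library and 1 row per gene symbol, 13341 in all, with no duplicated symbol and no summary row. The values deposited by the authors are a normalized read count signal, in which each gene's count is divided by a factor of its library. In every library 100% of the values were whole multiples of the value of 1 read, within a tolerance of 0.01, so whole reads were recovered. One read is worth 1.334, 0.8398 and 0.9079 in wild-type libraries 1 to 3 and 0.9052, 0.8595 and 1.187 in knock-out libraries 1 to 3. The lowest sum over the 6 libraries was 9 reads, so genes below some minimum appear to have been removed before deposit. All 6 columns were used. Recovered totals lie between 1508518 and 2383879 reads per library. Intervals and floors given for genes with few reads cover counting error only, since it is not known whether duplicates of 1 molecule were removed.

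Genes with a value of at least 10 in at least 3 libraries were tested, 10540 in all. The main test was limma 3.58.1 in R 4.3.3 with a variance trend, two-sided, on log2(value + 1), with the group as the only term and Benjamini-Hochberg adjustment at 0.05. It used the authors' scaling. Every adjusted p of a single gene in the results comes from this test unless another is named. Fold changes given beside a mean ± SD are ratios of the group means of normalized counts, and log2 changes and their standard errors come from the fit. Against a group with 0 reads the fold is a lower bound, computed with 3 reads over the group. With 1 to 3 reads in a group, the ratio of reads per library scale is given with an exact 95% binomial interval. The test assumes replicates from separate cultures, as the labels' word biological implies, and nothing in the labels says whether these came from separate animals.

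Before the data were examined, 29 gene lists were fixed: 18 of pathways, 8 of markers of liver cell types and 3 of RNA quality and sex. The pathway lists cover type I interferon-stimulated genes, cGAS-STING and nucleic acid sensing, interferon-gamma-type GTPases, MHC class I presentation, NF-kappaB and cytokines, fibrillar collagens and crosslinking, contractile genes, TGF-beta and YAP response, matrix proteases, quiescent stellate cell and retinoid genes, autophagy, NRF2 targets, cell cycle, p53 and senescence, endoplasmic reticulum and integrated stress, cholesterol biosynthesis, glycolysis and hypoxia, and oxidative phosphorylation. The markers are of hepatocytes, macrophages, endothelium, cholangiocytes and epithelium, mesothelium, portal fibroblasts, smooth muscle and pericytes, and lymphocytes and neutrophils. The others are mitochondrially encoded transcripts, immediate early and heat shock genes, and sex-linked genes. The 25 lists with at least 3 tested members were tested with camera of limma at a preset correlation of 0.01, each against all other tested genes, with adjustment over the lists. Camera with an estimated correlation and fry were alternatives.

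The genes to be named were fixed by rule at the same time. They are Nbr1, Sqstm1 and Sting1, then the 10 largest increases and 10 largest decreases among genes past the threshold with no overlap between the groups and a higher group mean of at least 50, leaving out predicted models, clone names and pseudogenes. From each list come up to 4 members with the smallest p, and any member needed to state a count of 5 or fewer. This gave 118 genes, of which the text names those that carry a comparison. Some of them are not reported here.

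Alternatives fixed at the same time were a pseudocount of 0.5 or 5, no filter, a mean of at least 50, TMM factors, quantile normalization, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, limma without a trend, an added threshold of 1.5-fold, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were a term for the 2 library sets, fits within each set, removal of the GC trend of transcript ends, and removal of each chromosome's median change. The library sets came from average-linkage clustering of each library's deviations from its group mean. These deviations are the spread that the main model leaves, so a term for the sets removes part of it by construction. The p-values of fits with that term can thus be too small. GC content was taken from the last 100 nucleotides of the longest GENCODE transcript for 96.5% of tested genes. The reference used here is GRCm38, another build than the authors', so it served only for names (92.4% of symbols found), neighbours, transcript ends and chromosome membership (98.6% of tested genes, assembly GRCm38.p6), and no coordinates are given.

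The procedure was tested on simulated counts drawn with the means, library totals and dispersions of these libraries. Genes were drawn independently and no shared difference between library sets was simulated, so the shares below may not hold for these libraries. For the comparison of the labelled groups, run on 10471 genes with 200 changed, limma called 20% of genes changed 2-fold, 86% of those changed 4-fold, 96% of those changed 8-fold and 100% of those changed 16-fold, with 8 unchanged genes among its 159 calls. DESeq2 called 40 unchanged genes among 202.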

Results

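Messenger RNA was measured in cultured mouse hepatic stellate cells, the vitamin A-storing pericytes of the liver that turn into collagen-producing myofibroblasts when activated. Cells labelled Nbr1 knock-out were set against cells labelled wild type, with 3 libraries in each of the 2 groups, and the labels call the 3 biological replicates. Nbr1 encodes an autophagy cargo receptor related to p62, the product of Sqstm1. All cells grew for 4 days in medium with 10% serum under basal conditions. Libraries were made from 200 ng of RNA with a kit that reads the 3' end of each transcript. The deposited table holds 13341 genes, and the reads recovered from it came to 1508518, 2383879 and 2177342 in wild-type libraries 1 to 3 and 2143285, 2276529 and 1648800 in knock-out libraries 1 to 3. The series addresses how NBR1 and p62 act on the STING pathway, the cytosolic DNA response that leads to interferon, in stellate cells during liver cancer.

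The libraries did not group by genotype label alone. Wild-type libraries 2 and 3 correlated at r = 0.984 across the tested genes, and knock-out libraries 1 and 3 at 0.981. Wild-type library 1 reached only 0.857 and 0.856 with the other wild-type libraries, below its 0.875 and 0.888 with knock-out libraries 1 and 3. Knock-out library 2 was closest to its own group, at 0.946 and 0.924 with knock-out libraries 1 and 3, and reached 0.901 and 0.903 with wild-type libraries 2 and 3. Genes that separated these library sets included Snhg8, at 17.3 normalized counts in wild-type library 1, 51.6 and 39.2 in knock-out libraries 1 and 3, and 793.6, 740.9 and 544 in the other 3 libraries. The ribosomal protein gene Rps23 showed the same split, with 48, 199.1 and 110.4 against 923.8, 979.7 and 688.4. Both genes were picked after their values were seen. By their deviations from the group means, one set held 1 wild-type and 2 knock-out libraries and the other the reverse. No 2 replicates were counted as 1 library deposited a second time. The chi-square of their reads over its degrees of freedom was 1.51 for wild-type libraries 2 and 3. It was 1.55 for knock-out libraries 1 and 3, and between 8.07 and 22.23 for the other pairs. This measure cannot tell separate cultures from repeat preparations of 1 culture.

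**Figure D1:**
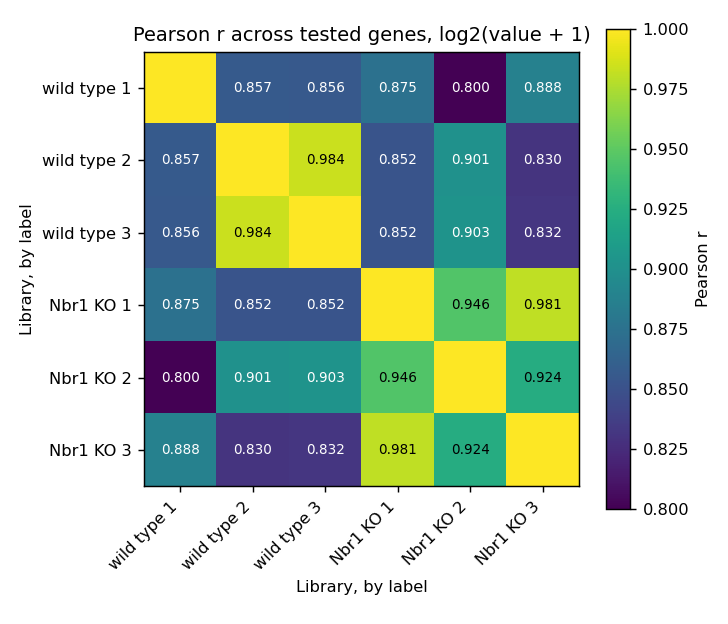
Pearson correlation between every 2 of the 6 libraries across tested genes, on log2(normalized count + 1), with libraries named by their labels on both axes and colour giving r from 0.8 to 1. Wild-type libraries 2 and 3 (0.984) and knock-out libraries 1 and 3 (0.981) form the closest pairs, while wild-type library 1 stays at or below 0.888 with every other library.

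The targeted gene was measured in every library. Nbr1 stood at 204.1, 278 and 288.7 normalized counts in the libraries labelled wild type and at 203.7, 188.2 and 175.6 in those labelled knock-out, or 256.9 ± 46.1 against 189.2 ± 14.1 (SD, n = 3 each). The log2 change of -0.43 (SE 0.18) did not pass the limma test (adjusted p = 0.22), although it did without wild-type library 1 (adjusted p = 0.0216). Within wild-type library 1 and knock-out libraries 1 and 3 the log2 change of Nbr1 was -0.11, and within the other 3 libraries it was -0.59. Each of these fits leaves 1 library in a group, so no p is given from them. Reads from the 3' end cannot show a deletion placed elsewhere in the gene, so this value does not check the labels. Sqstm1, which encodes p62, was nearly absent from the libraries labelled wild type, with 24, 10.9 and 12.7 normalized counts, and abundant in those labelled Nbr1 knock-out, with 817.4, 644.6 and 859.1. Its mean was 48.7-fold higher in the knock-out label (773.7 ± 113.7 against 15.9 ± 7.1, log2 change 5.59, SE 0.30, adjusted p = 0.000337). Sqstm1 is widely expressed in mouse tissues, so the groups are named below as the labels give them, and each direction rests on those labels. Sting1, which encodes STING, had 115.6 ± 42.6 normalized counts in the wild-type label and 167.4 ± 32.0 in the knock-out label (log2 change 0.57, SE 0.29, adjusted p = 0.308). The log2 change of Sting1 was 0.85 without wild-type library 1 (adjusted p = 0.027) and 0.52 among wild-type libraries 2 and 3 and knock-out library 2. It was 0.18 among the other 3 libraries and 0.20 with chromosome medians removed (adjusted p = 0.801).

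**Figure D2:**
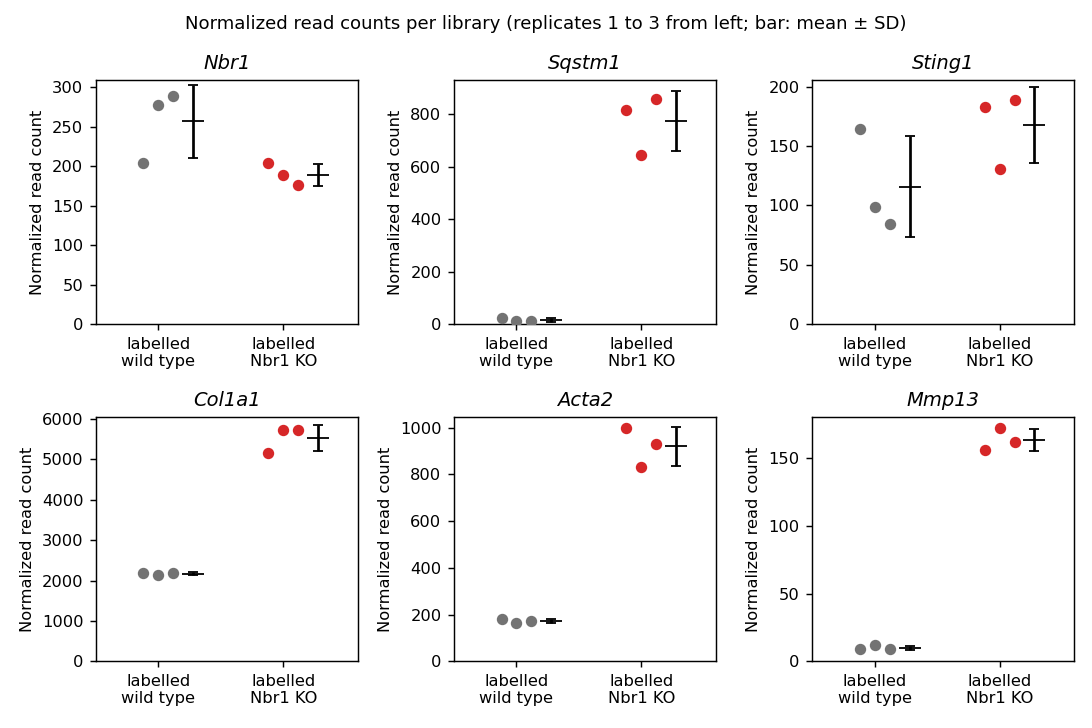
Normalized read counts of Nbr1, Sqstm1, Sting1, Col1a1, Acta2 and Mmp13 in each library (points, replicates 1 to 3 from left to right; grey, labelled wild type; red, labelled Nbr1 knock-out), with the mean and SD of each group beside them. Sqstm1 lies at or below 24 in the wild-type label and at or above 644.6 in the knock-out label, while the 2 groups of Nbr1 nearly touch, at 204.1 and 203.7.

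Between the labelled groups, 729 of the 10540 tested genes changed (limma, adjusted p under 0.05), 492 of them higher and 237 lower in the knock-out label. Among them, 197 were at least 4-fold higher and 74 at least 4-fold lower on the log2(value + 1) scale, which understates the change of low genes. For all 729 genes the 3 values of one group lay apart from the 3 of the other, as they did for 3173 tested genes (30.1%, where chance gives 10%). The count depended on the library sets. It rose to 2228 without wild-type library 1 and fell to 328 or 319 without wild-type library 2 or 3, and to 200, 338 or 231 without knock-out library 1, 2 or 3. All 729 genes had the same direction within both sets, but this was fixed in advance, since their groups do not overlap.

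**Figure D3:**
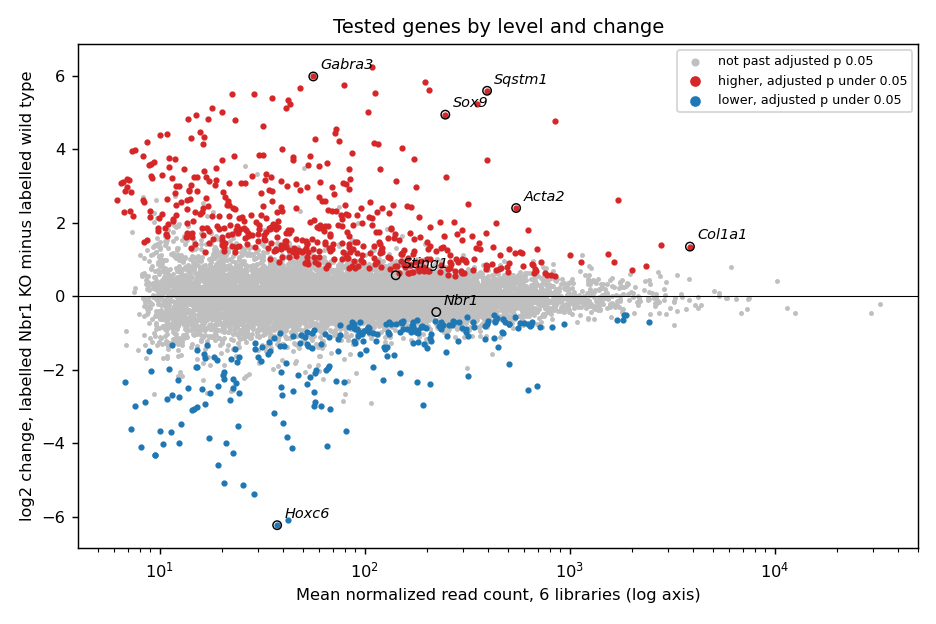
Mean normalized count over the 6 libraries (log axis) against the log2 change from the wild-type to the knock-out label for each of the 10540 tested genes. Red marks the 492 genes that were higher and blue the 237 that were lower at adjusted p under 0.05, grey marks the others, and circles mark named genes.

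The largest increases in the knock-out label were in genes of different kinds. Vat1l rose 62.7-fold (6.2 ± 3.4 to 388.8 ± 66.6 normalized counts), and the growth factor gene Ptn rose 51.9-fold (7.8 ± 3.7 to 404.6 ± 39.4). Postn, which encodes the matrix protein periostin, rose 82.2-fold (1.9 ± 0.7 to 156.2 ± 38.9), and Prelp, which encodes a leucine-rich matrix proteoglycan, rose 45.6-fold (4.8 ± 3.6 to 218.9 ± 17.3). Ctla2a, at 2.6 ± 2.5 against 214.0 ± 43.2, shares sequence with Ctla2b, so how its reads were assigned is uncertain. The imprinted non-coding RNA Meg3 rose from 1.1 ± 1.9 to 69.8 ± 19.1. For 3 other genes the wild-type label held 3 reads or fewer over the group. The read ratio was 111 for Gabra3, a GABA receptor subunit gene (95% exact interval 37.6 to 540), 95.2 for the homeobox gene Irx1 (32.2 to 464) and 179 for the basement membrane collagen gene Col4a6 (31.7 to 7110). Adjusted p ranged from 0.000337 for Postn, Ptn and Sqstm1 to 0.00433 for Meg3.

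The largest decreases included the homeobox gene Hoxc6, with 233 reads over the libraries labelled wild type and 0 in the knock-out label, at least 79.4-fold lower against a floor of 3 reads over the group. Hoxc13, of the same cluster, had 162 reads against 2, a wild-type to knock-out ratio of 82.8 (22.6 to 690). The membrane protein gene Itm2a had 259 reads against 1 (ratio 265, 47.1 to 10500), and the cell adhesion gene Cadm1 175 against 2 (ratio 89.5, 24.4 to 745). Padi3, which encodes a peptidyl arginine deiminase, fell 21.1-fold (84.5 ± 10.3 to 4.0 ± 1.7), and Prph, which encodes the intermediate filament peripherin, fell 16-fold (78.6 ± 11.8 to 4.9 ± 2.4). The RNA-binding protein gene Nova1 fell 14.4-fold (151.3 ± 69.0 to 10.5 ± 2.1). Stxbp6, Rnf112 and the lysophosphatidic acid receptor gene Lpar4 fell 12.5-fold, 9.45-fold and 8.68-fold. Adjusted p ranged from 0.000337 for Hoxc6 to 0.00507 for Rnf112. All 20 genes named for the size of their change passed in every alternative in which they were tested.

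Some genes of fibrous matrix and of the contractile myofibroblast were higher in the knock-out label. As sets, these 2 lists lost their calls with an estimated correlation (camera adjusted p = 0.106 and 0.171). Some markers of other mesenchymal cells also differed. Mesothelial markers were lower as a set (camera adjusted p = 0.00727, or 0.191 with an estimated correlation). Of 3 portal fibroblast markers, Thy1 was 11.4-fold higher, while Fbln2 and Cd34 did not pass (log2 change 0.50 and -0.74). The portal fibroblast list did not pass camera (adjusted p = 0.232). With no filter on low values, smooth muscle and pericyte markers were higher as a set (camera adjusted p = 0.00157 at the preset correlation). That list shares genes, Lmod1 among them, with the contractile list, and only 2 of its members passed the filter. Of 29 genes for fibrillar collagens and matrix crosslinking, 9 rose and 0 fell (13 and 0 adjusted over the list alone). Col1a1, the main fibrillar collagen gene, rose 2.55-fold (2169.4 ± 33.2 to 5538.8 ± 320.5), Col8a1 7.90-fold (18.8 ± 2.0 to 148.6 ± 19) and Loxl1, which encodes a crosslinking oxidase, 6.29-fold (17.0 ± 3.1 to 107.0 ± 9.4). Of 16 contractile genes, 6 rose and 0 fell (9 and 0 adjusted over the list alone). Acta2, which encodes smooth muscle actin, rose 5.30-fold (173.6 ± 8.7 to 920.8 ± 82.8), Tagln 9.82-fold (6.0 ± 2.1 to 58.9 ± 0.4) and the myosin light chain kinase gene Mylk 13.5-fold (9.0 ± 3.6 to 121.5 ± 40.3). Lmod1 had 0 reads in the wild-type label and 61 in the knock-out label, at least 19.9-fold higher. Of 18 matrix proteases and inhibitors, 6 rose and 0 fell (8 and 0 adjusted over the list alone). The collagenase gene Mmp13 rose 16.1-fold (10.1 ± 1.5 to 163.0 ± 8.2), the stromelysin gene Mmp3 12.6-fold (7.8 ± 3.7 to 98.1 ± 11.4) and the procollagen protease gene Adamts2 3.58-fold (58.6 ± 9.1 to 209.8 ± 14.3). As sets these lists moved up against other genes (camera adjusted p = 1.38e-08 for collagens, 4.41e-07 for contractile genes and 0.000461 for proteases). With an estimated correlation in place of the preset one the adjusted p was 0.106, 0.171 and 0.106, so none of these calls held.

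Some genes linked to the quiescent, retinoid-storing state were also higher in the knock-out label. Of 16 tested, 5 rose (Prelp, Aldh1a1, Dhrs3, Lhx2 and Hand2) and 0 fell, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00233; adjusted p = 0.124 with an estimated correlation). Aldh1a1, a retinaldehyde dehydrogenase gene, went from 459.0 ± 46.2 to 848.6 ± 61.2, and Lhx2, a transcription factor gene active in quiescent stellate cells, from 14.1 ± 2.0 to 39.2 ± 6.5. The call of Aldh1a1 was lost without wild-type library 2 or knock-out library 1 or 3 (adjusted p from 0.0514 to 0.0857). Those of Dhrs3, Lhx2 and Hand2 were lost without any 1 of wild-type libraries 2 and 3 and knock-out libraries 1 to 3 (adjusted p up to 0.154, 0.122 and 0.179). Among 24 TGF-beta and YAP response genes, 4 rose (Ltbp1, Tgfbi, Ltbp2 and Pmepa1) and 0 fell, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.232). The list passed, upward, in 2 of 20 alternatives. Among them was the fit with a term for the library sets (camera adjusted p = 0.042), sets drawn from these same data. The direction of the list turned down without wild-type library 1 (camera adjusted p = 0.954). Ltbp1, which encodes a binding protein of latent TGF-beta, rose 3.74-fold (56.5 ± 3.9 to 211.4 ± 36.1) and Tgfbi 5-fold (10.4 ± 1.3 to 52.0 ± 4.2). Ltbp2 and Pmepa1 lost their calls without any 1 of the same 5 libraries (adjusted p up to 0.0857 and 0.214).

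Cholesterol biosynthesis genes rose in part, with 4 of 22 higher, among them Msmo1, Cyp51 and Sqle, 0 lower, and 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000268; adjusted p = 0.106 with an estimated correlation). The sterol oxidase gene Msmo1 rose 2.74-fold (193.1 ± 25.2 to 528.5 ± 12.8). Cyp51 and Sqle lost their calls without any 1 of wild-type libraries 2 and 3 and knock-out libraries 1 to 3 (adjusted p up to 0.104 and 0.135). Cell cycle genes were lower as a set, with 4 of 38 lower (Cenpe, Ccna2, Ccnb2 and Nusap1) and 0 higher, the same counts adjusted over the list alone (camera adjusted p = 0.0393; adjusted p = 0.171 with an estimated correlation). Cenpe, which encodes a centromere motor, went from 816.9 ± 20.7 to 467.6 ± 3.5, and the cyclin gene Ccna2 from 714.4 ± 73.3 to 427.9 ± 34.0. The set call was lost without wild-type library 2 or 3 or knock-out library 2 (adjusted p = 0.0629, 0.0952 and 0.0638). The call of Cenpe was lost without knock-out library 1 or 3 (adjusted p = 0.072 and 0.0595), and those of Ccna2, Ccnb2 and Nusap1 without any 1 of the 5 libraries other than wild-type library 1 (adjusted p up to 0.151, 0.134 and 0.214).

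No list of interferon, STING pathway or inflammatory genes passed camera in the main test, while fry, which does not compare a list with other genes, gave an adjusted p of 0.0378 for cGAS-STING genes and 0.0341 for interferon-gamma-type genes, both up. Of 28 type I interferon-stimulated genes, 2 rose (Ifi47 and Ifi27) and 2 fell (Xaf1 and Lgals3bp), with 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.693). The interferon-inducible GTPase gene Ifi47 rose 3.84-fold (26.3 ± 4.7 to 101.1 ± 20.1) and Ifi27 2.52-fold (134.3 ± 20.6 to 337.9 ± 69.9). Xaf1 fell 6.31-fold (39.1 ± 10.9 to 6.2 ± 2.2) and Lgals3bp 2.66-fold (186.9 ± 64.6 to 70.2 ± 13.3). Each of these 4 calls was lost without knock-out library 1 or 3, Ifi27 also without wild-type library 3, Xaf1 also without wild-type library 2 or 3, and Lgals3bp also without wild-type library 2 or 3 or knock-out library 2 (adjusted p from 0.051 to 0.13). Of 20 genes of cGAS-STING and nucleic acid sensing, only Ifi203 rose (27.7 ± 11.9 to 96.1 ± 3.4) and 0 fell, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.468). Ifi203 belongs to a family of similar genes, so its reads are uncertain, and its call was lost without wild-type library 2 or any knock-out library (adjusted p from 0.073 to 0.125). Cgas, the DNA sensor gene, had 98.4 ± 9.3 and 60.2 ± 1.4 normalized counts (adjusted p = 0.0543; adjusted p = 0.0273 without wild-type library 1). Of 10 interferon-gamma-type GTPases and regulators, 0 changed in limma, edgeR or DESeq2 and 2 had an unadjusted p under 0.05, while 9 had a positive log2 change. The camera adjusted p of this list was 0.0554, and it passed in 8 of 20 alternatives. These included the fits without wild-type library 3 (camera adjusted p = 0.0403) or knock-out library 3 (0.0462), with no filter (0.0131) and with the replicate block (0.0468). The list also passed with a term for the library sets (0.0284), with chromosome medians removed (0.0383) and with fry. The last was the fit within wild-type library 1 and knock-out libraries 1 and 3, whose p is not given with 1 library in a group. Of 16 genes of MHC class I presentation, only the immunoproteasome gene Psmb8 rose, at 5.1 ± 3.3 against 27.4 ± 5.7, the same count adjusted over the list alone (camera adjusted p = 0.232). The list passed with a term for the library sets (camera adjusted p = 0.0284). It also passed within wild-type library 1 and knock-out libraries 1 and 3, a fit with 1 library in a group. The call of Psmb8 was lost without any 1 of the 5 libraries other than wild-type library 1 (adjusted p from 0.076 to 0.189). Of 18 NF-kappaB and cytokine genes, the chemokine genes Cxcl5 and Cxcl12 rose and 0 fell, the same counts adjusted over the list alone (camera adjusted p = 0.232, direction down). Cxcl12 went from 1524.3 ± 36.5 to 2512.3 ± 153.8, and its call was lost without any 1 of the same 5 libraries (adjusted p from 0.0529 to 0.0857). Cxcl5 had 3 reads against 35, and its call was lost without knock-out library 1 (adjusted p = 0.0607).

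The autophagy, NRF2, stress response, p53, glycolysis and oxidative phosphorylation lists did not pass camera in the main test. The glycolysis and hypoxia list passed, downward, with a mean of at least 50 (adjusted p = 0.0369) and with fry (0.0341), and the stress response list passed, upward, with fry (0.00768). Of 39 autophagy genes, Sqstm1 and Wipi1 rose and 0 fell, with 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.33). Wipi1, which encodes a protein of the forming autophagosome, had 36.9 ± 7.8 against 76.7 ± 4.9 and lost its call without any 1 of the 5 libraries other than wild-type library 1 (adjusted p from 0.0958 to 0.165). Of 24 targets of NRF2, the antioxidant regulator that p62 can activate through KEAP1, 0 changed in limma, edgeR or DESeq2 and 7 had an unadjusted p under 0.05 (camera adjusted p = 0.304; fry adjusted p = 0.0048, direction up). Slc7a11, the cystine transporter gene, stood at 4.3 ± 3.0 and 15.2 ± 2.2 (adjusted p = 0.0906; adjusted p = 0.04 without wild-type library 1). Of 21 stress response genes of the endoplasmic reticulum and integrated stress response, Herpud1 and Trib3 rose and 0 fell, with 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.173). Of 18 p53 and senescence genes only Btg2 fell, and of 20 glycolysis and hypoxia genes only Hk2 fell, with 0 higher and the same counts adjusted over each list alone (camera adjusted p = 0.44 and 0.232). Of 37 nuclear-encoded oxidative phosphorylation genes, 0 changed in limma, edgeR or DESeq2 and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.47). The calls of Trib3, Btg2 and Hk2 were lost without any 1 of the same 5 libraries (adjusted p up to 0.111, 0.174 and 0.145), and that of Herpud1 without knock-out library 1 or 3 (adjusted p = 0.0705 and 0.065).

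**Figure D4:**
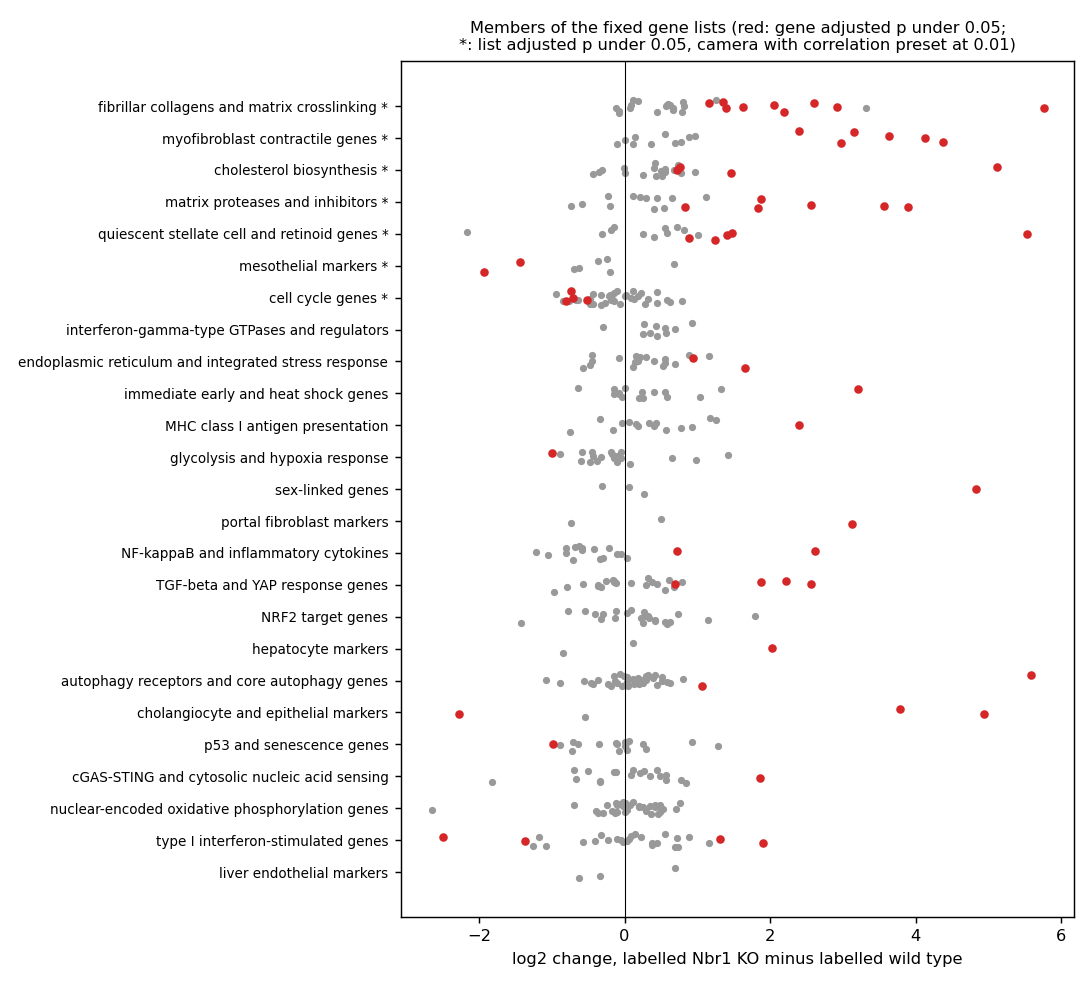
The log2 change from the wild-type to the knock-out label of each tested member of the 25 lists with at least 3 tested members (points, scattered vertically within a list; red, gene past adjusted p 0.05). An asterisk marks the 7 lists that moved as a set with the correlation preset at 0.01, of which 0 passed with an estimated correlation and 6 had an unadjusted p under 0.05 in that test.

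Markers of other cell types were checked in the same way. Mesothelial markers were abundant in both groups and lower as a set in the knock-out label, with 2 of 8 lower (Upk3b and Krt14), 0 higher, and 3 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.00727; adjusted p = 0.191 with an estimated correlation). Gpm6a had 1050.8 ± 125.5 and 813.0 ± 38.3 normalized counts, and Upk3b 181.5 ± 6.7 and 68.0 ± 17.9. The call of Upk3b was lost without wild-type library 3 or knock-out library 1 or 3, and that of Krt14 without any knock-out library (adjusted p from 0.051 to 0.099). Among 4 cholangiocyte and epithelial markers, Sox9 and Cdh1 rose and Tspan8 fell, with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.393). Sox9, a transcription factor gene, rose 31.3-fold (15.3 ± 5.8 to 478.6 ± 15.3). Cdh1 lost its call without knock-out library 1 or 3 (adjusted p = 0.0607 and 0.0527), and Tspan8 without any 1 of the 5 libraries other than wild-type library 1 (adjusted p up to 0.175). Of 3 portal fibroblast markers Thy1 rose (2.8 ± 1.2 to 31.8 ± 6.9), with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.232). Of 3 hepatocyte markers Trf rose 4.09-fold (91.8 ± 6.1 to 375.7 ± 11.9), the same count adjusted over the list alone (camera adjusted p = 0.33), while albumin (Alb) had 22.3 ± 6.2 and 13.0 ± 6.8. Of 3 endothelial markers 0 changed in limma, 1 in edgeR and 1 in DESeq2, with 1 at an unadjusted p under 0.05 and 1 higher adjusted over the list alone (camera adjusted p = 0.862; the median change was -0.34 and the direction of the test up). Of 2 tested smooth muscle and pericyte markers Lmod1 rose, with 2 higher adjusted over the list alone, and the list was too short for a set test in the main analysis. With no filter on low values it could be tested and passed camera, upward (adjusted p = 0.00157 at the preset correlation). Of 18 macrophage markers 3 were in the table, none above the filter, and of 17 lymphocyte and neutrophil markers 0 were in the table.

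Signs of RNA quality and of sex were also compared. Of 16 immediate early and heat shock genes only Hspa1a rose (1.7 ± 1.5 to 21.2 ± 4.8), the same count adjusted over the list alone (camera adjusted p = 0.192), and its reads cannot be told from those of the near-identical Hspa1b. Its call was lost without wild-type library 2 or any knock-out library (adjusted p from 0.0554 to 0.105). The 13 listed protein-coding mitochondrial transcripts had 0 members in the table. Of 4 tested Y-linked genes Uty rose, from 1 read to 106, the same count adjusted over the list alone (camera adjusted p = 0.232). Ddx3y had 160.8 ± 22.6 and 193.2 ± 19.2 normalized counts and Kdm5d 38.3 ± 5.1 and 39.8 ± 3.6.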

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

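The term for the library sets, the fits within each set and the removals of the GC trend and of chromosome medians were chosen after seeing the data, and the other settings before. The 20 genes named for the size of their change kept direction and call in every alternative in which they were tested, as did 38 of the 69 named genes past the threshold in all. Of the 49 others, 40 passed in at least 1 alternative. The 729 genes became 380 (241 higher, 139 lower, 376 shared) with a mean of at least 50, which tests fewer genes, and between 640 and 951 under the other pseudocounts, filter, scalings, tests and corrections, where edgeR called 719 of the 729 and DESeq2 722. In no alternative did any of the 729 pass with the opposite sign (0 genes). For fits on fewer libraries or with an added term this was fixed in advance, since the groups of these genes do not overlap. Leaving out 1 library gave 200 to 2228 genes (146 to 1277 higher, 54 to 951 lower), with fewer samples in each fit, and a log2 change of Nbr1 from -0.58 to -0.33. The replicate block gave 476 genes (127 lower, 456 shared), and the replicate numbers do not pair the libraries, since the deviations of same-numbered libraries correlated at 0.446, 0.7 and -0.624 and those of wild-type library 1 came closest to knock-out library 3 (0.698). A term for the 2 library sets gave 2791 genes (1503 higher, 1288 lower), with all 729 among them. The sets were drawn from the spread that this term removes, so the rise is in part built in. Within wild-type library 1 and knock-out libraries 1 and 3 there were 3932 (2206 higher, 1726 lower), and within the other 3 libraries 2993 (1452 higher, 1541 lower), where the lone library of an arm is assumed to vary like the other arm. The log2 change of Nbr1 was -0.11 in the former and -0.59 in the latter (adjusted p = 0.000662; the range over its alternatives was 0.000662 to 0.59). Ahsg, at 0.11 in all libraries, reversed to -1.25 there, and the cause was not tested. The 7 lists that moved as sets became 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 17 with fry, which does not compare a list with other genes, and between 6 and 9 elsewhere. Of the 7, cell cycle genes lost their call in 8 of 20 alternatives and the others only with an estimated correlation. Simulated 2-fold changes were called in 20% of cases and 4-fold changes in 86%, with no library sets in the simulation. How much of this comes from depth and how much from the spread between replicates was not tested.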

Other observations

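The tests of GC content as part of the library difference, of the Sqstm1 pattern, of the order of genes along chromosomes and of chromosome copies were chosen only after their results had been seen at least in part, as were the genes and gene groups of the next paragraphs.

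Genes expressed from 1 parental copy, known as imprinted genes, differed between the labelled groups. Of 21 tested, 8 were higher in the knock-out label (Grb10, Dlk1, Meg3, Igf2, Slc38a4, Cdkn1c, Ndn and Plagl1) and 2 lower (H19 and Impact) in limma. Grb10 went from 18 ± 6.5 to 688.1 ± 40.7 normalized counts, Dlk1 from 5.2 ± 1.7 to 138.7 ± 13.5 and Igf2 from 39.4 ± 15.3 to 202.8 ± 19, while its neighbour H19 went from 341.1 ± 132.6 to 42.7 ± 15.7 (SD, n = 3 each). The calls of Grb10, Dlk1, Meg3, H19 and Slc38a4 held without each library in turn, and that of Igf2 was lost without knock-out library 1 (adjusted p = 0.0549). Those of Cdkn1c and Impact were lost without any 1 of the 5 libraries other than wild-type library 1, that of Ndn without wild-type library 3 or any knock-out library, and that of Plagl1 without wild-type library 2 or any knock-out library (adjusted p from 0.0587 to 0.153). Without wild-type library 1, Mest, Ube3a, Peg3 and Ppp1r9a also passed, all lower (adjusted p = 0.00139, 0.00872, 0.0418 and 0.044). DESeq2 on all libraries also called Mest and Ube3a, both lower (adjusted p = 0.00629 and 0.027). The number of lower genes thus depended on the setting. The list was written after 5 of its genes had been seen. Of its other 16 tested members 5 changed, or 31.2% against 6.8% of the remaining genes (exact Fisher test across genes, which are not independent, two-sided p = 0.00349). This share counts calls of the main test, and those of Cdkn1c, Impact, Ndn and Plagl1 did not hold without each library in turn. The Fisher test was not repeated with a library left out.

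Homeobox genes of the Hox C cluster, which mark position along the body axis, were nearly silent in the knock-out label. All 5 tested genes of the cluster fell (Hoxc4, Hoxc6, Hoxc9, Hoxc10 and Hoxc13; adjusted p from 0.000337 to 0.00287), with 0 reads of Hoxc4 and Hoxc6 and 1 or 2 of the others over the 3 libraries. In the Hox A cluster 1 of 7 rose (Hoxa5) and 1 fell (Hoxa10), and in the Hox B cluster 1 of 8 rose (Hoxb8) and 1 fell (Hoxb7). Hoxa5, Hoxb7 and Hoxb8 lost their calls without any 1 of the 5 libraries other than wild-type library 1, Hoxa10 without wild-type library 2 or 3 or knock-out library 1 or 3 (adjusted p from 0.0554 to 0.16), and Hoxb8 also after quantile normalization (adjusted p = 0.0563). Hoxb9 passed with TMM factors (adjusted p = 0.0468), edgeR, DESeq2 and without wild-type library 1. The ubiquitin gene Ubb went from 61.8 ± 22.3 to 1624.3 ± 260.3 (adjusted p = 0.00064), and since it belongs to a family of similar sequences, part of its reads is uncertain. The receptor gene Pdgfrb, a stellate cell and pericyte marker, went from 36.8 ± 13.7 to 138.3 ± 12.9 (adjusted p = 0.0143), a call lost without knock-out library 1, 2 or 3 (adjusted p = 0.0923, 0.0616 and 0.0688).

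Other splits of the 6 libraries bear on the counts. There are 10 splits into 3 and 3, too few for a share under 0.05. For the number of genes, 2 of the 10 gave a count as large as the real 729, and the highest other count was 1379, for wild-type library 1 with knock-out libraries 1 and 3 against the rest, which points to a structure of the libraries apart from the labels. With that structure as a term the labels gave 2791 genes, a rise in part built in, since the structure was drawn from these libraries' own spread. For gene lists, 1 of the 10, the real one, gave 7 or more, and the highest other split gave 5.

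In the set of wild-type library 1 and knock-out libraries 1 and 3, 579 genes were at least 4-fold lower than in the other set within the wild-type label and 134 within the knock-out label, 121 of them in both, and the contrasts between the sets correlated at r = 0.77 across genes between the labels. A different number of sampled reads is argued against, since after thinning all libraries to 1508518 reads the correlation was still 0.75. GC content of transcript ends may be part of the cause: genes with AT-rich ends were lower in that set, and Spearman's rho with GC across genes was 0.41 and 0.4 in the 2 labels. As the whole cause it is argued against, since the correlation was 0.74 after the GC trend was removed from each library. No biological explanation was tested, as the labels name no difference between replicates.

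The near absence of Sqstm1 from the libraries labelled wild type did not come from the library sets, since the smaller of the log2 changes within the sets was 5.07. Loss of a region holding most of the 10 nearest tested neighbours is argued against too, as their median log2 change was -0.2. They ranged from -0.88 to 2.39, and a median cannot show loss of a smaller region, which stays open. That the libraries labelled wild type may come from cells of another genotype, such as cells lacking Sqstm1, stays open, since such a difference would go with the labels and cannot be told apart from other differences between the cultures. There were 8 other tested genes that changed at least as strongly, a count that does not decide it. An effect of Nbr1 loss on Sqstm1 also stays open as untested, and nothing in these libraries checks the Nbr1 genotype.

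Whole chromosomes were shifted between the labelled groups, with a median log2 change from the wild-type to the knock-out label of 0.4 on chromosome 16, 0.37 on 18, 0.32 on 12 and -0.45 on 3, the 4 over 0.3 in size, and r = 0.97 between the library sets across 20 chromosomes. The GC trend is argued against, since these medians were 0.4, 0.36, 0.33 and -0.45 after its removal, and so is a chance order of genes that move with their neighbours (permutation p = 2e-04 over 10000 circular shifts of the gene order). On chromosomes 3, 12 and 16, and also on the less shifted 6 (-0.25) and 14 (-0.26), 100% of windows of 20 neighbouring genes lay on the side of the shift, and 96.4% on 8 and 92% on 10, consistent with the hypothesis that the groups of cells differ in copies of some chromosomes, which no DNA measurement here tests and which goes with the labels. On chromosome 18 only 61.5% of windows did, which argues against a difference in copies of the whole of that chromosome and leaves a part of it open. With each chromosome's median removed, 640 genes changed, 571 of them among the 729.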
